A study of Homo sapiens with 2 samples.

How the data were processed

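The series holds 2 single-cell 5' gene expression libraries from 1 resected tumor. Cells were sorted by their HS196 signal into a negative gate (bottom 25%) and a positive gate (top 2%), and each gate is 1 library. The labels disagree on the tumor, since the series concerns prostate cancer and the sample labels give colon; the deposited annotation names prostate zones. Per the submitters' processing notes, reads were processed with Cell Ranger 2.1.0, STAR 2.7.3a and Partek against hg19.

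Each deposited file gives 1 score per gene and cell, which the authors computed as log2 of CPM (counts scaled to library size) plus a pseudocount of 1, with 7 annotation rows above the genes. The deposited log2 values were turned back into CPM and, from the smallest steps within each cell, into UMIs. Values within 0.05 of a whole number made up 99.9977% and 99.9996% of the recovered UMIs in the negative and positive files. The deposited total and mitochondrial rows are sums and shares of log values and were not used. All CPM values below use the recovered total of each cell. Of 16299 gene rows, 90 were left out (XIST, Y-linked genes and antibody and T cell receptor V, D and J segments), and 16209 were used. The reference annotation in hand is of another genome build than the deposited counts, so no coordinates are given.

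Barcodes with fewer than 200 genes or more than 20% mitochondrial UMIs were left out. This kept 1045 of 1150 negative and 1264 of 1428 positive barcodes, with 4818763 and 13578042 UMIs. The main results use the deposited classes and 12 deposited graph clusters. Rebuilt clusters had been planned as the main classes; they are given as an alternative because the deposited classes carry the submitters' own names. The rebuilt clusters were first named from summed UMIs, which let 1 cell's hemoglobin name macrophage clusters; this was replaced, after the first output was seen, by means of per-cell log values. Marker genes were checked in each cluster. The leading genes of cluster 2 held 3 B cell, 2 mast cell, 1 plasma cell and 0 T cell markers. Its summed markers were nevertheless highest for T cells, 1970 CPM against 1360 for plasma cells, 831 for B cells and 805 for mast cells. IGHA1 gave 1087 CPM of the plasma cell sum, and nearly all of its negative-library UMIs came from 1 cell. Because the markers of cluster 2 were mixed, the class deposited as CD8 T cells was compared within itself only for gene copies and HSP90 genes. Clusters 2, 4 and 5 are given by number.

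UMIs were summed over the cells of each library or class, scaled to CPM, and compared as log2 ratios of positive over negative, with exact conditional binomial 95% intervals. A gene with 0 UMIs in a group was set to a floor of 3 counts over that group. Genes named per comparison follow a rule fixed before the data were examined. They are the first 12 genes in each direction for the whole library and the first 8 for a class, ranked by the interval bound nearest to 0, among those with at least 50 UMIs over both sums, a mean of at least 50 CPM and at least a 2-fold change. Other genes named are members of the fixed lists or marker lists, except H3F3A, H3F3AP4, PFN1 and PSCA, which were chosen after their values were seen. The comparisons, alternatives, 28 gene lists and 22 marker lists were also fixed then. Comparisons within Transition zone cells, cluster 3 and cluster 4 were added after the shares were seen. A list's median covers genes with at least 10 UMIs over both sums, and its percentile is taken among 10000 random lists from the same 20 expression bins. List examples are taken from the members with the most UMIs, and some genes are not reported here. No p-value or standard error is given, since each group holds 1 library. Counts of genes by size of change are given only for the fixed lists and the check of gene copies.

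The 28 lists were HSP90 paralogues, HSP90 co-chaperones, HSP90 client proteins, heat shock factor 1 response, endoplasmic reticulum chaperones, immediate early and dissociation response, cell cycle, glycolysis, hypoxia response, nuclear oxidative phosphorylation, androgen response, epithelial to mesenchymal transition, interferon response, NF-kappa-B and inflammatory cytokines, class I and class II antigen presentation, lysosome and endocytic uptake, complement and alternative macrophage markers, T cell activation and exhaustion, cytotoxic effector, naive and central memory T cell, efflux and uptake transporters, ferroptosis, antioxidant and iron, proteasome, apoptosis, mitochondrially encoded genes, ribosomal proteins, and housekeeping.

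In the tests of depth, both libraries were given equal cell weight in each of 10 bins of UMIs per cell; these replaced tests on thinned cells, which could not have moved a ratio. Shares of cells with a UMI were computed after thinning each cell to 1000 UMIs, leaving out cells below that depth. Alternatives were trimmed-mean and median-of-ratios scaling (own numpy functions), a total without mitochondrial and ribosomal genes, means over cells, a mitochondrial limit of 10%, no cell filter, thinning to 500 UMIs or none, removal of called doublets, and clusters rebuilt at several resolutions, without the named genes and in each library alone. Procedures were tested on simulated data. There, 95.8% of intervals held the true ratio over 13070 genes, and 90% and 92% of log2 changes of 1 and -1 had intervals excluding 0. The simulated sums held counting error only, as the intervals assume, and no spread between cells. These rates therefore do not test the intervals for genes whose UMIs sit in few cells. Software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scanpy 1.11.5, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.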

Results

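Epithelial cells were the largest class among the HS196-positive cells kept from this tumor, and cells of the lymphocyte clusters made up most of the HS196-negative cells. HS196 is a near-infrared probe joined to a drug that binds HSP90, a chaperone that folds many signaling proteins. The positive gate took the top 2% of the HS196 signal and the negative gate the bottom 25%. After filtering, 1045 HS196-negative cells and 1264 HS196-positive cells remained. Cells of the positive library were deeper, with a median of 9844.5 UMIs per cell against 3723, and with a median of 2393 genes per cell against 1146. Each group is 1 library from the same tumor, so there are no replicates, and no difference between the groups has a replicate check. Intervals are 95% and cover counting error only.

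Cells of the EPCAM+ class, named for an adhesion protein of epithelial cells, rose from 79 cells to 754 cells. Their share was 7.56% (6.03 to 9.33) of the negative library and 59.7% (56.9 to 62.4) of the positive library. The positive share depended on the mitochondrial limit. At 10% in place of 20% it was 39.0%, below the 47.3% then held by macrophages and neutrophils together. Macrophages, which take up particles and debris, rose from 10.4% (8.64 to 12.4) to 24.1% (21.8 to 26.6). The class deposited as Neutrophils rose from 1.05% (0.527 to 1.88) to 5.70% (4.48 to 7.12). Its genes include both neutrophil and monocyte markers. The lymphocyte clusters fell together, cluster 2 from 33.0% (30.2 to 36.0) to 2.77% (1.94 to 3.83), cluster 4 from 22.4% (19.9 to 25.0) to 2.06% (1.35 to 3.0), and cluster 5 from 17.6% (15.3 to 20.1) to 1.58% (0.969 to 2.43). These clusters make up nearly all of the class deposited as CD8 T cells. Endothelial cells, which line vessels, were 4.02% (2.91 to 5.39) of the negative and 1.58% (0.969 to 2.43) of the positive library. Fibroblasts, the matrix-making cells, were 4.11% (2.99 to 5.50) and 2.45% (1.67 to 3.46). Intervals are exact Clopper-Pearson intervals. Among cells outside the EPCAM+ class, macrophages still rose from 11.3% to 59.8% and the CD8 T cells class fell from 78.8% to 16.1%. Shares are of sorted and captured cells, and give no share of HS196-positive cells within a class.

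**Figure D1:**
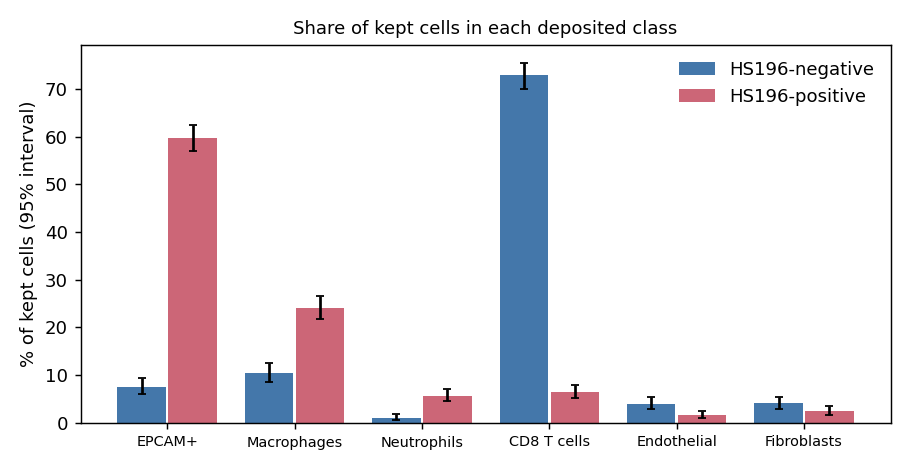
Share of kept cells (%) in each deposited class for the HS196-negative library (1045 cells) and the HS196-positive library (1264 cells); bars are shares and whiskers are 95% Clopper-Pearson intervals. The EPCAM+ bar rises from 7.56% to 59.7%, and the CD8 T cells bar falls from 72.8% to 6.49%.

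The epithelial cells themselves differed between the gates. The deposited annotation divides the EPCAM+ class into a Peripheral Zone, which held the cells rich in the secreted protease KLK3 (prostate-specific antigen), and a Transition zone. The Peripheral Zone held 6 of 79 EPCAM+ cells, 7.59% (2.84 to 15.8), in the negative library and 336 of 754, 44.6% (41.0 to 48.2), in the positive library. By graph cluster, cluster 1 rose from 6.33% to 43.6% of EPCAM+ cells and cluster 6 from 13.9% to 24.7%. Cluster 7 fell from 39.2% to 22.8%, and cluster 9 from 40.5% to 8.89%. Cluster 9 was shallow, with median depths of 2973 UMIs in the negative and 3806 in the positive library. Cluster 7 had 10815 and 13738.5, so the fall of cluster 9 is not told apart from a fall in shallow barcodes. Macrophages shifted too, with cluster 3 at 67.9% of the class in the negative and 97.4% in the positive library. Nearly all other macrophages lay in cluster 12, whose leading genes include the dendritic cell marker CLEC9A. Its median depths were 1247.5 UMIs in the negative and 1280.5 in the positive library, against 7439.5 and 7552 in cluster 3. The shift is thus also one in shallow barcodes. The deposited zones were used as named, but their markers also divide cell types. Over both libraries, cluster 1, which holds most Peripheral Zone cells, had 72641 CPM of luminal and 692 CPM of basal or club markers. Clusters 6, 7 and 9 of the Transition zone had 1049, 316 and 2160 CPM of luminal markers. Their basal or club markers summed to 32706, 8448 and 23224 CPM. The zones are therefore not told apart from luminal and basal or club cell types. With 6 negative cells, the Peripheral Zone was compared between the gates only for HSP90AA1.

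Summed over all cells, genes of secretory prostate epithelium were far higher in the HS196-positive library. MSMB, a secreted protein of prostate fluid, rose from 8.09 to 11960.6 CPM (UMIs scaled to library size), a log2 ratio of 10.53 (10.08 to 11.02). The secreted phosphatase ACPP rose by a log2 ratio of 8.83 (8.31 to 9.41). The proteases KLK3 and KLK2 rose by 6.64 (6.47 to 6.82) and 5.97, from 55.8 and 43.6 CPM. The transporter SLC45A3 rose by 6.38, the metalloreductase STEAP2 by 5.71, and the neuropeptide NPY by 5.68. The secreted phospholipase PLA2G2A rose by 5.61, the iron-binding protein LTF by 5.67, the filament protein NEFH by 7.04 and the transcription factor MESP1 by 5.40. POTEG rose by 9.81 (7.33 to 15.11) from 1 UMI in the negative library, and its near-identical copies make its own level uncertain.

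Genes of cytotoxic lymphocytes, antibodies and hemoglobin were the most reduced. CD8A, the co-receptor of killer T cells, fell from 173 to 3.17 CPM, a log2 ratio of -5.77 (-6.25 to -5.33). PRF1 and GZMB, which carry out target killing, had log2 ratios of -5.90 and -5.51. The chemokine XCL2 had -5.79, the T cell receptor constant segment TRBC2 -5.51, the proteoglycan SPOCK2 -5.44, and the CD45-associated PTPRCAP -5.26. The antibody genes IGHA1 and IGLC2 had -11.34 and -10.84, but 98.2% and 99.2% of their negative-library UMIs came from 1 cell. IGHA2, with 0 UMIs in the positive library, had a log2 ratio at or below -9.18 against the floor of 3 counts, and 97.9% of its negative UMIs came from 1 cell. The hemoglobin genes HBB and HBA2 had -9.78 and -5.93, with 49.4% and 53.0% of their negative UMIs in 1 cell. Sums over a library mix the shares of the classes with changes within them.

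Gene lists fixed before the data were examined moved the same way as the classes. The androgen response list had the highest median log2 ratio over the whole library, 2.81 over 16 measured genes, 13 of them at least 2-fold higher. Its best-covered members were KLK3, KLK2 and ACPP. The cytotoxic effector list had the lowest median, -5.45, followed by T cell activation and exhaustion at -3.76, the naive and central memory T cell list at -3.23, and the cell cycle list at -1.92. The complement and alternative macrophage list had a median of 0.90, with APOE at 0.90, C1QC at 0.91 and C1QB at 0.76. The lysosome and endocytic uptake list had 0.85, with CD63 at 1.01, PSAP at 1.33 and CTSD at 1.74. Nuclear oxidative phosphorylation had 0.78, ferroptosis, antioxidant and iron genes 0.66, mitochondrially encoded genes 0.60, and endoplasmic reticulum chaperones 0.56. Each of these 6 medians lay above at least 96.2% of 10000 random lists matched for size and expression.

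The remaining lists had whole-library medians between -1.0 and 0.32. Median log2 ratios were 0.32 for the hypoxia response, 0.30 for NF-kappa-B and inflammatory cytokines, 0.27 for the proteasome and 0.23 for glycolysis. They were 0.06 for ribosomal proteins, 0.04 for HSP90 client proteins, -0.01 for class II antigen presentation, -0.03 for apoptosis and -0.06 for the interferon response. Lower medians came from housekeeping genes, -0.11, efflux and uptake transporters, -0.22, immediate early and dissociation genes, -0.53, epithelial to mesenchymal transition, -0.82, and class I antigen presentation, -0.84. Of these last 5, only the immediate early, mesenchymal transition and class I lists lay below 99% of the matched random lists.

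HSP90AA1, the stress-inducible HSP90 gene, was lower in the HS196-positive library as a whole. It was higher within most cell sets of that library, with cluster 5 and the Peripheral Zone as exceptions. Over the whole library it was 6905 CPM in the negative and 3122 CPM in the positive library, a log2 ratio of -1.15 (-1.17 to -1.12). Its constitutive paralogue HSP90AB1 had -0.63, the endoplasmic reticulum paralogue HSP90B1 0.76, and the mitochondrial paralogue TRAP1 0.39 (0.02 to 0.77). Within EPCAM+ cells HSP90AA1 was 1285 CPM in the negative and 1932 CPM in the positive library, 0.59 (0.49 to 0.69). The zone mix enters that value, since the ratio was 0.22 within the Transition zone and -0.19 (-0.36 to -0.01) within the Peripheral Zone, with 6 negative cells in the latter. Its log2 ratio was 0.57 within endothelial cells, 1.14 within fibroblasts and 0.17 (-0.06 to 0.42) within the class deposited as Neutrophils. Cluster 4 lymphocytes held 8286 CPM in the negative and 9649.5 CPM in the positive library, cluster 2 held 9836 and 12808 CPM, and cluster 5 went the other way, from 11666 to 7789 CPM. The gap between macrophages and EPCAM+ cells exceeded the gap between the gates in either. In the negative library macrophages held 5.05-fold (4.70 to 5.43) the HSP90AA1 of EPCAM+ cells, and in the positive library 3.71-fold. The gap was not particular to HSP90AA1. The heat shock genes compared were all higher in macrophages, HSPA1A by 7.58-fold and 5.85-fold, whereas HSP90B1 and TRAP1 were lower there.

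The heat shock factor 1 response list holds mostly chaperones, only some of them stress-induced, and HSF1 itself. It had a whole-library median of -1.0 over 20 genes, below all matched random lists. Averaging the ratios within classes instead gave a median of 0.0411. HSPA1A had a log2 ratio of -1.52, HSPA1B -0.99 and the small chaperone HSPB1 -0.36, and HSPA1A and HSPA1B are near-identical copies. Co-chaperones of HSP90 had a median of -0.26, with FKBP4 at -1.0, CDC37 at -0.23 and PTGES3 at -0.19. The 4 HSP90 paralogues had a median of -0.12. With every cell thinned to 1000 UMIs, HSP90AA1 had a UMI in 55.7% of negative and 65.8% of positive EPCAM+ cells, and in 72.9% and 88.8% of macrophages. Cluster 4 stood at 91.9% in the negative library and at 100% (86.8 to 100) in the 26 cells of the positive library. No deposited class should lack this gene, so no background share exists for it.

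**Figure D2:**
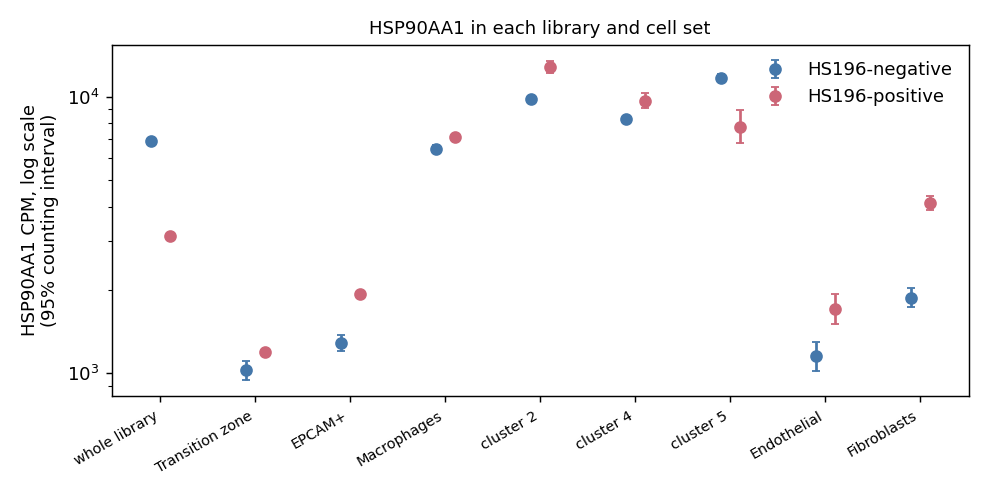
HSP90AA1 in CPM on a log axis in the HS196-negative and HS196-positive libraries, for the whole library and for cell sets within it; points are pooled levels and whiskers 95% counting intervals. The whole-library level falls from 6905 to 3122 CPM while the EPCAM+ level rises from 1285 to 1932 CPM.

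Within the EPCAM+ class, the secreted proteins MSMB and KLK3 were higher in HS196-positive cells and the basal keratin KRT14 was lower. MSMB rose from 34.2 to 15924 CPM, a log2 ratio of 8.86, and KLK3 from 375.8 to 7422 CPM, 4.30 (4.13 to 4.48). ACPP had 6.63, NEFH 5.99, the surface protein CD177 6.52 (4.04 to 11.83), the matrix protein SPON2 4.88 and LTF 4.60. POTEG had 0 UMIs in the negative cells and a log2 ratio of at least 5.86. Among Transition zone cells alone NEFH and SPON2 were lower in the positive library instead, and CD177 and POTEG had too few UMIs for a ratio. All 16 androgen response genes were at least 2-fold higher, with a median of 1.97. KRT14 had -4.30. The smooth muscle genes ACTA2 and TAGLN had -6.74 and -5.19, the growth factor IGF2 -5.29, KRT6A -3.23 and the activin inhibitor FST -3.14. A top cell held 86.5% of the negative ACTA2 UMIs, 71.7% of TAGLN, 97.1% of IGF2, 44.4% of KRT6A and 63.3% of FST. CHGA, a neuroendocrine granule protein, had -7.45 and all 133 of its negative UMIs came from 1 cell. POTEF, with near-identical copies, had -3.52. Median depth was 7833 UMIs in the 79 negative and 13580 in the 754 positive cells, and the changed share of the Peripheral Zone enters every value here.

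Transition zone cells, compared after the zone shares had been seen, leave the Peripheral Zone out. They still mixed clusters by gate, with 31 of 73 negative and 62 of 418 positive cells in cluster 9, and 11 and 184 in cluster 6. In 418 HS196-positive against 73 HS196-negative cells, class II antigen presentation genes, HMOX1 and CCL20 were higher. The trimmed-mean scaling moved this comparison by -0.206 and the median-of-ratios scaling by -0.190, so values in this paragraph are relative to the trimmed-mean shift. HMOX1, which breaks down heme, rose from 66.3 to 568 CPM, 3.30 (2.86 to 3.79). The chemokine CCL20 rose from 218 to 1286 CPM, 2.76 (2.52 to 3.02). The class II genes HLA-DRB1 and HLA-DPA1 rose by 3.12 and 2.93. HLA-DRB1 was also higher in HS196-positive macrophages, by 0.998 (0.914 to 1.08) relative to the macrophage scaling shift. In macrophages HLA-DPA1 had 0.08 and the class II list a median of 0.10. Whether an offset of HLA-DRB1 shared by cell sets enters its Transition zone value was not tested. The steroid-converting enzyme AKR1C2 rose by 3.17, the reductase DHRS2 by 2.76 and the synuclein SNCG by 2.57. HSPA6, a strictly stress-induced chaperone, rose by 2.60, although 64.2% of its negative UMIs came from 1 cell. KRT14 fell from 228 to 17.3 CPM, -3.52 (-3.90 to -3.13), and KRT6A from 754 to 124 CPM, -2.39. ACTA2, TAGLN and IGF2 had -6.86, -5.27 and -5.10 and rested largely on 1 negative cell each. POTEF, FTH1P2 and PFN1P1, all copies of other genes, had -3.15, -2.53 and -2.32.

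The class II, interferon, NF-kappa-B and heat shock factor 1 lists were higher in the HS196-positive Transition zone cells. The immediate early and dissociation list had 0.06, and mitochondrially encoded genes had 0.44, with a median mitochondrial share of 8.06% in negative and 10.49% in positive cells. The class II list, which holds the genes that present antigen to helper T cells, had a median of 1.84 relative to the shift, with 8 of 10 genes at least 2-fold higher. CD74 had 1.28 and HLA-DRA 1.84. The interferon response list had 0.76, with IRF1 at 0.92, OAS1 at 2.13 and IFI6 at -0.05. The NF-kappa-B list had 0.63, with NFKBIA at 0.63, SOD2 at 0.45 and CXCL1 at 0.12. The lysosome list had 0.53, the heat shock factor 1 list 0.50 (0.29 without the shift removed) and nuclear oxidative phosphorylation 0.49. On the same scale, housekeeping genes had 0.24, ribosomal proteins 0.22 and the proteasome 0.27, so values near these are not set apart from them. Within the heat shock list HSPA1B had 1.05, HSPA1A 0.58 and HSPB1 0.19. HSP90AA1 had 0.43 (0.31 to 0.55) and, without the shift removed, 0.22 (0.11 to 0.34). That unshifted value became 0.0216 at a mitochondrial limit of 10%. HSP90AB1 had 0.39 (0.26 to 0.52), HSP90B1 0.03 (-0.14 to 0.21) and TRAP1 -0.43 (-1.02 to 0.20). The mesenchymal transition list had -1.26, with 8 of 10 genes at least 2-fold lower, among them THBS1 at -1.29 and SNAI2 at -1.90. The androgen response list had 0.21. Median depth was 7318 UMIs in negative and 13597 in positive cells. The shallow cluster 9, with medians of 2973 and 3806 UMIs, enters that gap.

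HS196-positive macrophages held more APOC1, more of several metallothionein transcripts and more lysosomal transcripts than HS196-negative macrophages. The comparison covers 305 against 109 cells, with median depths of 7308 and 5816 UMIs. Within cluster 3 the median depths were close, 7552 and 7439.5 UMIs. The scaling shift was -0.104 by trimmed mean and -0.106 by median of ratios, and values in this paragraph are relative to the former. APOC1, a lipoprotein component, rose from 258 to 1575 CPM, 2.71 (2.49 to 2.94). Among the metal-binding metallothioneins named by the rule, MT1G rose by 2.60 (2.43 to 2.77), MT1M by 3.01, MT1A by 3.30 and MT1F by 2.74. MT1L and MT1HL1 had 4.68 and 3.39, and the split of counts among these near-identical copies is uncertain. PLA2G2A had 5.12, with 53.4% of its UMIs in 1 cell. HBB and HBA2 had -10.60 and -8.79, with nearly all negative UMIs in 1 cell. The copies POTEF, PFN1P1 and FTH1P2 had -3.31, -2.74 and -2.05.

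Gene lists gave the same picture of HS196-positive macrophages. The lysosome list had a median of 0.74 relative to the shift, with 10 of 28 genes at least 2-fold higher. The proteases CTSD and CTSB had 1.88 and 0.77, and the sphingolipid activator PSAP 1.17. The iron list had 0.65, with the ferritin chains FTL and FTH1 at 1.04 and 0.61, GPX1 at -0.08 and HMOX1 at 1.05. Endoplasmic reticulum chaperones had 0.58, with HSPA5 at 1.14, CALR at 0.33 and HERPUD1 at 0.25. Complement and alternative macrophage markers had 0.49, with APOE at 1.63, C1QC at 0.66, C1QB at 0.49 and the lipid-associated GPNMB at 2.34. HSP90AA1 had 0.25 (0.20 to 0.30), HSP90AB1 0.55, HSP90B1 0.48 and TRAP1 1.44 (-0.62 to 4.59). On the same scale, housekeeping genes had 0.19, ribosomal proteins 0.12 and the proteasome 0.02, so HSP90AA1 stood close to the housekeeping median. The heat shock factor 1 list had 0.06 and the cell cycle list -0.61. The class mixed cluster 3 with cluster 12, and within cluster 3 alone the lysosome list had 0.71 and the iron list 0.79.

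Cluster 4, compared after its fall had been seen, held fewer killing transcripts in the HS196-positive library. The comparison covers 26 HS196-positive against 234 HS196-negative cells, with a scaling shift of 0.106 by trimmed mean and 0.099 by median of ratios. Relative to the former, the cytotoxic effector list had a median of -1.12, with 8 of 14 genes at least 2-fold lower. The protease inhibitor CST7 had -1.56 (-2.23 to -0.96), GZMB -1.17 (-1.94 to -0.48) and the granule protein NKG7 -0.40 (-0.96 to 0.12). Mast cell genes rose in the same cluster, TPSAB1 from 75.7 to 693 CPM, 3.09 (2.60 to 3.58), CPA3 by 3.03 and TPSB2 by 2.28. Cells of another type, free RNA and doublets were not told apart as their source. The cytotoxic fall may therefore not lie within 1 cell type. The T cell activation list had -0.88, with CD69 at -1.22, and the class I list -0.79. The naive and central memory list had 0.42, but its best-covered members had intervals that include 0, IL7R at 0.10 (-0.14 to 0.33), CCR7 at 0.37 (-0.08 to 0.79) and LTB at 0.42 (-0.25 to 1.04). HSP90AA1 had 0.11 (0.02 to 0.21). With 26 positive cells, differences for single genes of low level were not detectable at this depth.

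**Figure D3:**
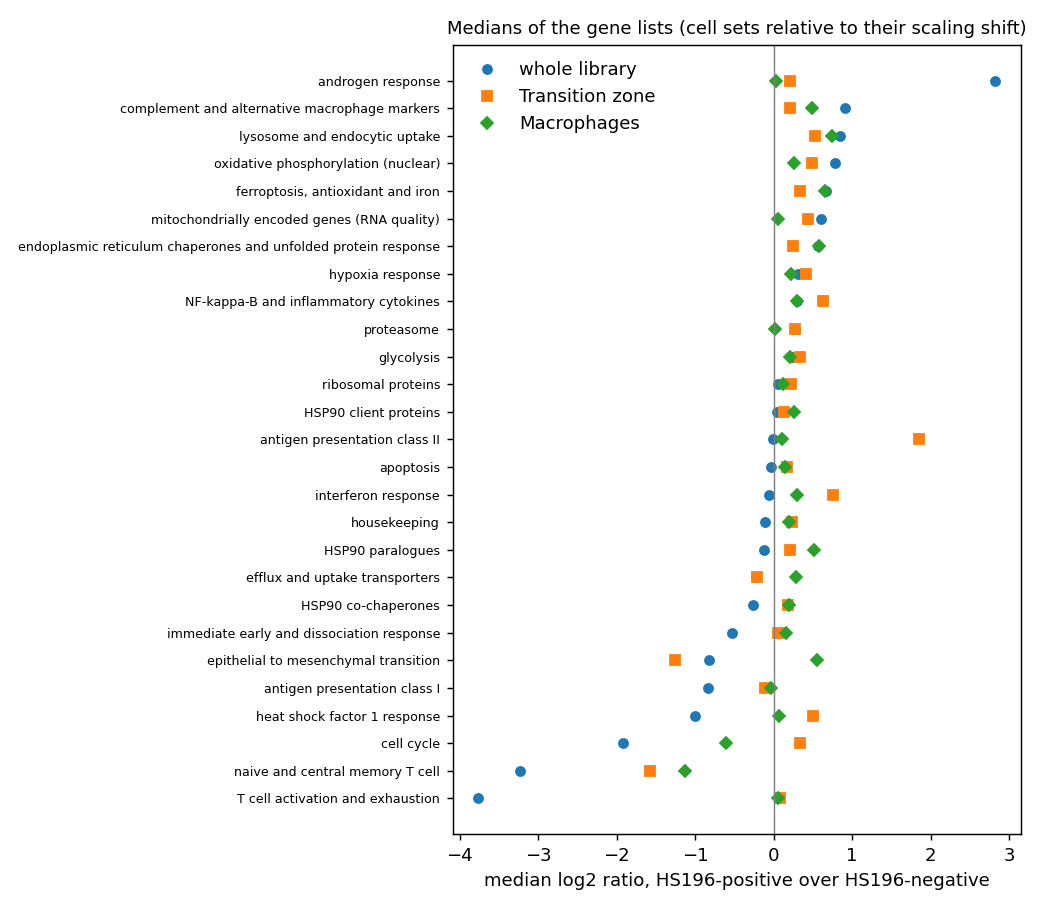
Median log2 ratio of HS196-positive over HS196-negative for the fixed gene lists other than the cytotoxic effector list (not measured in Transition zone cells), over the whole library, in Transition zone cells and in macrophages; points are medians, and those of the cell sets are relative to their scaling shift. The androgen response list stands at 2.81 over the whole library and at 0.21 in Transition zone cells.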

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

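All tests in this part were chosen only after the result was seen, except the 2 on doublets and on cluster 7 in the class II pattern.

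Gene lists moved in opposite directions in different cell types, and none of these differences was itself tested. Values here are not corrected for the scaling shift. The mesenchymal transition list had a median log2 ratio of -1.47 in Transition zone cells and 0.44 in macrophages. The NF-kappa-B list had 0.43 in Transition zone cells and -0.41 in cluster 4. The naive and central memory T cell list had -1.78 in Transition zone cells, -1.24 in macrophages and 0.53 in cluster 4. Most of its genes are scarce in Transition zone cells and macrophages. CCR7 is not scarce in macrophages, at 571 CPM in the negative and 242 CPM in the positive library.

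Red blood cell barcodes, a deposited class removed by the cell filter and used in no comparison, differed between the gates. They were 59 barcodes, 5.13% (3.93 to 6.57), of the negative library and 5 barcodes, 0.350% (0.114 to 0.815), of the positive library.

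HSP90AA1 was lower in the HS196-positive library sum by a log2 ratio of -1.15, while macrophages, Transition zone cells and cluster 4 each held more of it and cluster 5 held less, 7789 against 11666 CPM. With the positive library's classes reweighted to the class mix of the negative library, its level became 8021 CPM and the log2 ratio 0.22, so the cell mixture is a candidate explanation for the whole drop. With cells of both libraries matched for depth, at means of 6116 and 6201 UMIs, a ratio of -0.55 (-0.58 to -0.52) remained, and since depth goes with cell class its part in the drop cannot be told apart from the mixture. A stronger dissociation stress in the negative library would leave HSP90AA1 lower in the positive cells of each class, yet the lowest ratio in macrophages, Transition zone cells and cluster 4 was 0.14 (0.10 to 0.19) before and 0.11 (0.02 to 0.21) after removal of the scaling shift. Before that removal it was 0.0216 for Transition zone cells at a mitochondrial limit of 10%, and 0.0514 for macrophages of cluster 3 alone. The Peripheral Zone, with 6 negative cells, went the other way at -0.19 (-0.36 to -0.01). Stress stays open for cluster 5 and the Peripheral Zone, as does an untested difference in HSP90 protein or probe binding. The immediate early medians of Transition zone cells, macrophages and cluster 4, -0.15, 0.05 and -0.25, were tried first and decide nothing.

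Some gene copies were offset alike in EPCAM+ cells, macrophages, cluster 8 and the class deposited as CD8 T cells, the 4 cell sets examined, with 11 genes at least 2-fold lower and 12 higher by a log2 ratio above 0.5 among 1751 compared. H3F3A had log2 ratios from -2.01 to -1.78 across these sets, its copy H3F3AP4 from 1.01 to 1.31, and their sum from 0.24 to 0.48, whereas the fall of PFN1P1 in EPCAM+ cells, -2.67, was not offset by PFN1 at -0.20, with a sum of -0.50. Among the 23 offset genes, 78.3% carried copy or clone names, against 12.5% of all genes compared, so reads counted to different copies in the 2 libraries are a candidate explanation. Depth per cell is argued against by H3F3A, which stayed at -1.71 (-1.91 to -1.52) in cells matched for depth. No biological explanation was tested.

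Class II transcripts were higher in Transition zone cells of the HS196-positive library, with a list median of 1.64. Free macrophage RNA would carry all abundant macrophage genes, yet the median macrophage gene stood at 0.644% of its macrophage level there and class II genes at 4.12%, with LYZ an exception at 7.14%. The class II list median stayed at 1.39 without cells holding a UMI of C1QA, C1QB, C1QC, TYROBP, AIF1, FCER1G, APOC1 or CCL3. That left 72 negative and 357 positive cells. LYZ and APOE were not part of that filter, and LYZ had a UMI in 5.48% of negative and 17.7% of positive Transition zone cells. Some doublets may thus remain. The class II median was 1.66 in cells matched for depth, over 8 class II genes against 10 for the full value. Within cluster 7 (31 negative and 172 positive cells) it was 1.77 over 7 genes. It was 1.66 within cluster 9 but 0.66 within cluster 6, which held 11 negative cells, so a part of the cluster mixture stays open there. Cluster 9 was shallow, with median depths of 2973 UMIs in the negative and 3806 in the positive library. A difference in class II expression between the gates in clusters 7 and 9 may be biological, as a hypothesis from 1 tumor that was found and tested on the same data.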

How the results depend on the processing

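Tests with the Transition zone alone, cluster 3 alone and clusters without the named genes were chosen only after the result was seen, and clusters rebuilt at resolution 1, first meant as the main classes, became an alternative only then. No paired analysis was possible because each group holds 1 library. Over the alternatives, 73 values of the class shares stayed within the counting interval and 15 moved beyond it, without changing which library was higher. For the lists that answer a comparison, 68 values stayed, and for the other lists 862 stayed and 31 moved. For other named genes within classes, 368 values stayed, 63 moved and 3 reversed; over the whole library, 155 stayed and 34 moved. Except as stated the cause was not tested.

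With at most 10% mitochondrial UMIs, the EPCAM+ share was 5.82% and 39.0%, the positive share of clusters 2, 4 and 5 9.54%, of macrophages with neutrophils 47.3%, and of cluster 1 among EPCAM+ cells 28.4%. HSP90AA1 was then -0.89 over the whole library, 0.21 in EPCAM+ and 0.0216 in Transition zone cells. With every barcode, the positive EPCAM+ share was 62.7%, macrophages with neutrophils 26.7%, and the negative share of clusters 2, 4 and 5 68.6%. Clustering each library alone gave 5.06% for those clusters in the positive library.

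The negative share of luminal cells among EPCAM+ cells, cluster 1 in the deposited clusters, was 0 with clusters rebuilt at resolution 1 and with each library alone, 16.3% at resolution 0.5 and without the named genes, and 18.5% at resolution 2; the positive share was 39.7% at resolution 1. These rest on 92 negative cells in the rebuilt clusters and 80 with each library alone.

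HSP90AA1 over the whole library was -1.08 with a total without mitochondrial and ribosomal genes and -0.94 as a mean over cells. It was 0.22 in EPCAM+ cells restricted to the Transition zone. In Transition zone cells it was 0.43 with trimmed-mean and 0.41 with median-of-ratios scaling. In macrophages both scalings gave 0.25, the mean over cells 0.54, and cluster 3 alone 0.0514.

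Taking the mean of within-class log2 ratios, the heat shock factor 1 list reversed to 0.0411 and the androgen list moved to 1.14. Restricting EPCAM+ cells to the Transition zone reversed HSP90B1 to -0.17, NEFH to -1.70 and SPON2 to -2.18, by leaving out the Peripheral Zone, and left CD177 and POTEG at or under the floor of 3 counts in both libraries, with no ratio.

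Depth limits the share of cells with an HSP90AA1 UMI. At 500 UMIs it was 36.7% of negative and 48.3% of positive EPCAM+ cells, and 62.4% and 79.7% of macrophages. Unthinned, it was 82.3% and 97.7% of EPCAM+ cells, 97.7% of positive macrophages and 100% of negative cluster 4, which stood at 95.1% with at most 10% mitochondrial UMIs.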

Other observations

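The comparisons in this part were chosen only after the result was seen, and no tests were run on them.

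Within the HS196-positive library, the 2 deposited zones of the EPCAM+ class differed widely. Peripheral Zone cells held 16458 CPM of KLK3 and Transition zone cells 64.9 CPM, with a KLK3 UMI in 97.9% and 22.7% of cells. Macrophages of that library, which should lack KLK3, had a KLK3 UMI in 12.8% of cells at a median depth of 7308 UMIs. The surface antigen FOLH1 stood at 86.3 against 0.357 CPM and the long noncoding RNA PCA3 at 20.6 against 0 CPM. SCGB3A1, a secretoglobin, went the other way, from 228 to 11198 CPM, and so did the surface protein PSCA, from 121 to 1813 CPM. HSP90AA1 was 2842 CPM in Peripheral Zone and 1192 CPM in Transition zone cells, 2.38-fold (2.32 to 2.46). Median depths were close, 13571.5 and 13597 UMIs.

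Lists divided the zones as well, given as Peripheral Zone over Transition zone. The androgen response list had a median log2 ratio of 3.85, the lysosome list 1.03, the hypoxia list 0.87 and the heat shock factor 1 list 0.56. The immediate early and dissociation list had 0.45, and the median mitochondrial share was 12.8% in Peripheral Zone and 10.49% in Transition zone cells. The class II list had -1.93, the NF-kappa-B list -1.62, apoptosis -1.20, glycolysis -1.03 and the interferon list -0.67.

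Epithelial genes had UMIs in other classes, whether from free RNA, doublets or misplaced cells, which were not told apart. Over 12 epithelial genes in the positive library, the median was 0.409% of the EPCAM+ level in macrophages (0.192 to 2.48), 0.900% in the class deposited as Neutrophils (0.177 to 8.37) and 1.07% in the class deposited as CD8 T cells (0.244 to 4.22), with the range over genes in parentheses. In the negative library the medians were 0.247% (0 to 51.9), 0 and 0.699% (0.0863 to 3.11). Called doublets were 3 of 1045 negative cells and 14 of 1264 positive cells, 13 of them in the EPCAM+ class.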
